A study of Mus musculus with 4 samples.

How the data were processed

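The series measured transcript levels in mouse heart with Affymetrix 3' expression arrays, in which biotin-labelled cRNA made from total RNA is hybridised to short oligonucleotide probes and the probes of a transcript are summarised as a probe set. There were 4 arrays, 2 of heart samples from mice carrying a Ser9Ala replacement in GSK-3beta and 2 of samples from wild-type mice, all at baseline. Group and replicate number came from the sample titles. The 2 wild-type samples also served a sister comparison with GSK-3alpha knock-in mice, and per the labels they were normalized here only with the GSK-3beta knock-in arrays. The deposited values were log2 expression values. Per the submitters' processing notes they were made with RMA (background correction, quantile normalization and median polish) in Affymetrix Expression Console, whose version is not given in the sources used here. RMA gives no detection call, so a dim probe set has a value even where its transcript is absent. The number of arrays, not read depth, limits the precision.

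The table held 45101 probe sets, of which 64 were controls. The platform annotation gave 1 gene symbol for 34945 probe sets, several symbols for 932 and no symbol for 9160. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, which held 34741 of the 34945. That table also gave the order of genes along the chromosome. None of its coordinates are printed, because the sources used here name no build. Each gene was represented by the probe set with the highest mean over the 4 arrays, which left 18193 genes. Control probe sets and those with several symbols or none were not in the gene test. When the 10092 left-out probe sets other than controls were fitted together with the named ones, none passed and 498 had an unadjusted limma p under 0.05. No filter on dim probe sets was applied.

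Knock-in minus wild-type differences were estimated with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a trend or robust prior, and tested two-sided with Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. Errors of group means are SDs with n = 2. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, so the test relied on limma's pooling of the spread across genes. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists with at least 5 measured members. Of these, 23 were pathways, 12 were markers of cell types that a heart sample can hold and 4 were technical. Within each list, p-values were also adjusted over the list alone. Genes within 10 Mb of Gsk3b were compared with all others by Fisher's exact test, two-sided, counting genes with an unadjusted limma p under 0.01 because fewer than 20 genes passed. The test of genes near Gsk3b was included because a knock-in allele made in embryonic stem cells can keep flanking sequence of the cells' strain.

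The gene, list and Gsk3b window tests, the 39 lists, the alternatives and the rule for named genes were fixed before the data were examined, whereas the tests of explanations in the closing section were chosen later. The rule took 10 genes per direction, first those that passed and then those of smallest p among genes with a mean above the median of all genes, with both knock-in arrays beyond both wild-type arrays and with a log2 difference of at least 0.5. It added Gsk3b, Gsk3a, 12 metabolic, stress and Wnt genes (Ppara, Cd36, Fabp3, Lpl, Acsl1, Pdk4, Cpt1b, Nppa, Nppb, Myh6, Myh7 and Axin2), Xist and the Y-linked genes, and up to 4 members of smallest p for each list described. Acsl1 and Cpt1b were not analysed here. A further list of 56 liver genes, lists of clock genes in phase with Dbp or with Arntl, and a list of genes raised by fasting or glucocorticoids were drawn up after the first results had been seen.

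The gene test was tried on simulated data with the real gene means. Spreads were drawn at random from the prior that limma fitted to these arrays, not taken from each gene. Noise was normal and independent between genes, so the recovery assumes the model that limma itself fits. In 10 runs with 18193 genes, of which 200 were changed in each, 84.2% of genes changed 2-fold and 99.4% of genes changed 4-fold were recovered, with 7.4 false calls per run on average. A list shifted by 0.3 was called in 10 of 10 runs, with 0 calls among unshifted lists. Because the simulated genes varied independently, these runs cannot show how often lists of correlated genes are called falsely. Alternatives were the replicate number as a block, an intensity trend with robust prior, centring or quantile normalization of the arrays, genes above the median alone, other ways of choosing probe sets, a test against a minimum fold change of 1.2 (treat), other list tests (an estimated correlation in camera, and fry for a shift one way and for change in either direction), other windows around Gsk3b and leaving out each array in turn. With 4 arrays, camera with an estimated correlation and fry for a shift one way rest on few residual degrees of freedom. They can then hardly call a list, so a call lost there does not decide whether the list shifted. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.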

Results

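GSK-3beta is a serine/threonine kinase that is inhibited when its serine 9 is phosphorylated, and the Ser9Ala replacement removes that site. Heart samples numbering 2 from knock-in mice aged 3.5 months and 2 from wild-type mice aged 3.6 months, all labelled C57B6, were compared at baseline to ask how the replacement changes cardiac gene expression. Array medians over all probe sets lay between 5.97 and 6.04 on the log2 scale. Across the 18193 genes tested, Pearson's r between arrays ran from 0.994 to 0.997, where genes are not independent replicates. The median absolute log2 difference between arrays averaged 0.128 for pairs from different groups and 0.120 for pairs within a group. The smallest, 0.108, was that of wild-type 2 and knock-in 1, while the wild-type arrays differed by 0.132. Among genes above the median the averages were 0.125 between groups and 0.106 within them. Pearson's r there was 0.991 and 0.994 within the groups and 0.986 to 0.990 between them.

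Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was 3.19-fold lower in knock-in hearts, at 10.70 ± 0.10 in wild-type and 9.02 ± 0.06 in knock-in hearts (log2, mean ± SD, n = 2). It was the only gene to pass the test, with an adjusted p of 0.0434 from limma and both knock-in arrays below both wild-type arrays. No gene passed in the higher direction under this test, whereas 12 of the 22 that passed with an intensity trend and robust prior were higher, 7 of 11 with each array centred or quantile normalized, 8 of 11 with averaged probe sets and 3 of 7 among genes above the median. At an unadjusted limma p under 0.05 there were 800 genes higher and 544 lower in knock-in hearts, 1344 in all where chance gives 910. Both knock-in arrays lay beyond both wild-type arrays in 36.5% of genes, where chance gives 33.3%. The unadjusted split depended on the fit. With each array centred on its median it became 1145 higher and 392 lower, and over all probe sets other than controls 1278 higher and 1350 lower. Over all alternatives between 0 and 22 genes passed, and the adjusted p of Cdkn1a ran from 0.00176 to 0.420. Without knock-in 2, 677 genes had an unadjusted limma p under 0.05. The Cdkn1a call was lost without any 1 of the arrays (adjusted p of 0.229 without wild-type 1, 0.323 without wild-type 2, 0.151 without knock-in 1 and 0.408 without knock-in 2), where the lone array of a group is assumed to vary like the others, and also with the probe set listed first (0.0706) and against a minimum change of 1.2-fold (0.0709).

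Among the brighter genes whose arrays lay apart by group, those of smallest p after Cdkn1a included clock, liver, stress and metabolic genes, and none of them passed over all genes. Higher values in knock-in hearts were seen for the clock output genes Dbp (9.11 ± 0.45 against 11.42 ± 0.13, a 4.97-fold difference), Per3 (3.53-fold) and Ciart (3.28-fold). Serpina1c and Serpina1b, which encode the liver-secreted protease inhibitor alpha-1-antitrypsin and are near-identical copies that a probe set may not tell apart, were 4.97-fold and 4.37-fold higher. Timmdc1, a mitochondrial complex I assembly factor that lies near Gsk3b, was 2.90-fold higher, at 9.54 ± 0.06 in knock-in hearts. Cideb, a lipid droplet protein abundant in liver, was 1.76-fold higher, and Scfd2, E330017L17Rik and Gm16793 were 1.71-fold to 1.94-fold higher. Lower values were seen for Pdk4, the kinase that inhibits pyruvate dehydrogenase (12.92 ± 0.36 against 11.34 ± 0.34, 2.99-fold), for 2210407C18Rik (2.82-fold), for the mTORC1 inhibitor Ddit4 (2.54-fold) and for the mitochondrial carrier Ucp3 (2.05-fold). The hyaluronan receptor Cd44, the endoplasmic reticulum chaperone Hyou1, Arhgap31, Cyb5a and the interferon-induced Ifit1 were 1.67-fold to 1.83-fold lower. The adjusted p from limma was 0.0724 for Ciart, Dbp, Timmdc1, 2210407C18Rik, Ddit4 and Ucp3, and from 0.142 to 0.220 for the others. Per3 differed by -0.11 with the probe set listed first. In the plot of these genes by array, every knock-in value lies on one side of both wild-type values, which the rule for choosing them required.

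**Figure D1:**
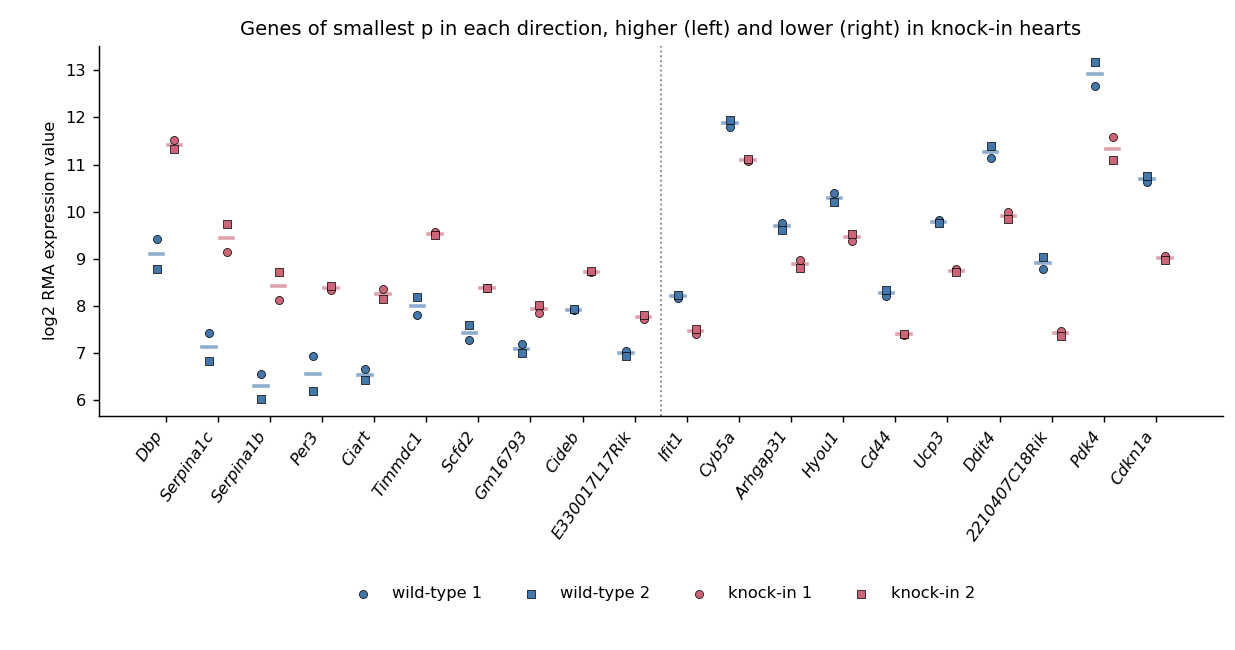
Log2 RMA expression values of the 20 genes of smallest p under the naming rule, 10 higher in knock-in hearts to the left of the dotted line and 10 lower to the right, where each point is 1 array (circles replicate 1, squares replicate 2) and bars are group means. Cdkn1a, at the far right, is the gene that passed, with 10.70 in wild-type and 9.02 in knock-in hearts.

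Gsk3b itself was at 9.67 ± 0.07 in wild-type and 9.85 ± 0.04 in knock-in hearts, and Gsk3a at 10.76 ± 0.06 and 10.80 ± 0.05. Neither passed (adjusted p of 0.761 for Gsk3b from limma). The difference was -0.17 for Gsk3b when its probe sets were averaged and -0.00288 for Gsk3a after quantile normalization. A transcript array cannot check the amino acid change that the labels give. The nuclear receptor Ppara differed by 0.13 (-0.12 without wild-type 1, 0.38 without wild-type 2 and -0.00598 without knock-in 1), the fatty acid transporter Cd36 by -0.09, the fatty acid binding protein Fabp3 by 0.08 (-0.19 with averaged probe sets) and lipoprotein lipase Lpl by 0.00 on the log2 scale, none past the threshold. Of the hypertrophy markers, 4 had been chosen beforehand and none of them passed, with differences of 0.06 for Nppa, 0.23 for Nppb (-0.06 without wild-type 1), 0.08 for Myh6 (-0.21 with averaged probe sets, -0.49 with the first probe set) and 0.01 for Myh7 (-0.03 after quantile normalization), and the Wnt target Axin2 differed by 0.16. Xist was at 6.59 ± 0.13 in wild-type and 6.41 ± 0.12 in knock-in hearts, and Eif2s3y at 7.86 ± 0.08 and 7.88 ± 0.05. Differences of the other Y-linked genes (Kdm5d, Uty, Usp9y, Zfy2 and Sry) lay between -0.19 and 0.18.

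The circadian clock genes that passed within their list went in opposite directions for different limbs of the clock. Adjusted over the list alone, 10 of the 21 measured members rose and 3 fell in knock-in hearts, and 8 did not pass. The 10 were Ciart, Dbp, Per3, Tef, Per2, Hlf, Nr1d2, Usp2, Cry2 and Bhlhe40, most of them transcribed when the BMAL1 and CLOCK proteins are active, and Tef and Per2 were 2.13-fold and 2.04-fold higher. The 3 were Arntl, which encodes BMAL1 (8.79 ± 0.38 against 7.43 ± 0.30, 2.55-fold lower), Clock (1.66-fold lower) and Npas2 (1.42-fold lower), the activating limb itself, while Cry1, a repressor in phase with Arntl, differed by 0.48 without passing. The list was shifted higher in camera (median 0.45, adjusted p = 2.93e-06), a call that was lost at adjusted p = 0.956 with an estimated correlation. With 4 arrays the latter test can hardly call any list, so the loss does not decide whether the clock list shifted. No clock gene passed over all genes, and the 13 are all named because they passed within the list. The labels do not give the time of day at which hearts were collected.

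At camera's preset correlation 4 stress, immune and matrix lists were shifted lower in knock-in hearts, but none of these calls held with an estimated correlation (adjusted p = 0.956) or with fry, and most members did not pass. Both of these other list tests can hardly call a list with 4 arrays, so the lost calls leave the shifts undecided. Of the 32 measured targets of the unfolded protein response and ATF4, 10 fell and 1 rose adjusted over the list alone, and 21 did not pass. Those that fell included Ddit4 and the endoplasmic reticulum chaperones Hspa5 (1.62-fold), Calr (1.60-fold) and Sdf2l1 (1.83-fold), and the one that rose was Ddit3 (1.25-fold), which encodes the stress transcription factor CHOP. The list was shifted lower in camera (median -0.07, adjusted p = 1.51e-04), a call lost at adjusted p = 0.956 with an estimated correlation. Its median was -0.0133 without wild-type 2, where the adjusted p was 0.148, -0.11 without wild-type 1 and -0.12 without knock-in 1. Of 29 interferon response genes, 5 fell adjusted over the list alone and none rose, namely the GTPase Iigp1 (11.29 ± 0.48 against 9.95 ± 0.15, 2.54-fold), the antiviral Rsad2 (1.85-fold), Oasl2 (1.68-fold), Ifit1 (1.67-fold) and Rtp4 (1.46-fold), and 24 did not pass. Their list had a median of -0.15 (-0.37 without knock-in 2) and an adjusted p of 1.27e-08, and adjusted p = 0.956 with an estimated correlation. Of 27 NF-kB and inflammatory genes only the inhibitor Nfkbia fell adjusted over the list alone (1.45-fold), in a list with a median of -0.09 and an adjusted p of 0.00666, and adjusted p = 0.956 with an estimated correlation. That list was at adjusted p = 0.339 without wild-type 2 and at 0.0696, with a median of -0.06, without knock-in 1. None of the 35 extracellular matrix genes passed adjusted over the list alone, where the smallest p belonged to Mmp14 (-0.52), Timp1 (-1.22), Col14a1 (0.45) and Eln (-0.63), in a list with a median of -0.11 and an adjusted p of 0.0120, and adjusted p = 0.956 with an estimated correlation. The matrix median was -0.07 without knock-in 1, where the adjusted p was 0.160, -0.04 without wild-type 1 and -0.18 without wild-type 2. With each array centred the medians were -0.03 for the unfolded protein response, -0.06 for the NF-kB list and -0.07 for the matrix list. Among genes above the median they were -0.30 for the interferon list and -0.23 for the NF-kB list, and with averaged probe sets -0.23 for the interferon list.

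At camera's preset correlation 2 fatty acid lists were shifted lower and the glucose list higher in knock-in hearts relative to all other genes, but none of these calls held with an estimated correlation (adjusted p = 0.956) or with fry, and most members did not pass. Here too, both of these other list tests can hardly call a list with 4 arrays. Of the 37 genes of fatty acid oxidation and PPAR alpha targets, 4 fell adjusted over the list alone, none rose and 33 did not pass. The 4 were Pdk4, Ucp3, Angptl4, a secreted inhibitor of lipoprotein lipase (9.17 ± 0.38 against 8.10 ± 0.07, 2.11-fold), and the acyl-CoA thioesterase Acot1 (1.92-fold), none of which is an enzyme of the beta-oxidation spiral. All 4, like Cdkn1a and Ddit4, also belong to the later list of genes raised by fasting or glucocorticoids. Apart from Cdkn1a, Pdk4, Ddit4 and Ucp3, which had been seen to be lower, that list had 29 measured members. Of these, Angptl4 and Acot1 among them, 18 were lower and 11 higher in knock-in hearts (median -0.11). Of 16 genes of fatty acid uptake and activation only the hormone-sensitive lipase Lipe fell adjusted over the list alone (1.71-fold). Both lists were shifted lower in camera with an adjusted p of 0.00666 each, and both calls were lost at adjusted p = 0.956 with an estimated correlation and at 0.160 without wild-type 2. Their medians were -0.08 for uptake (-0.05 with each array centred, -0.15 with averaged probe sets) and -0.02 for oxidation. The latter became 0.0144 with each array centred, -0.07 after quantile normalization, -0.00804 without wild-type 1, -0.04 without wild-type 2 and -0.05 without knock-in 2. Of 24 genes of glucose uptake and glycolysis, 2 rose adjusted over the list alone, Pfkfb2, which makes the activator of phosphofructokinase (8.61 ± 0.14 against 9.30 ± 0.17, 1.61-fold), and the pyruvate dehydrogenase phosphatase Pdp1 (1.39-fold), while the insulin-responsive transporter Slc2a4 differed by 0.27 without passing. The list had a median of 0.13 (0.08 without knock-in 2) and an adjusted p of 6.40e-04, and adjusted p = 0.956 with an estimated correlation.

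**Figure D2:**
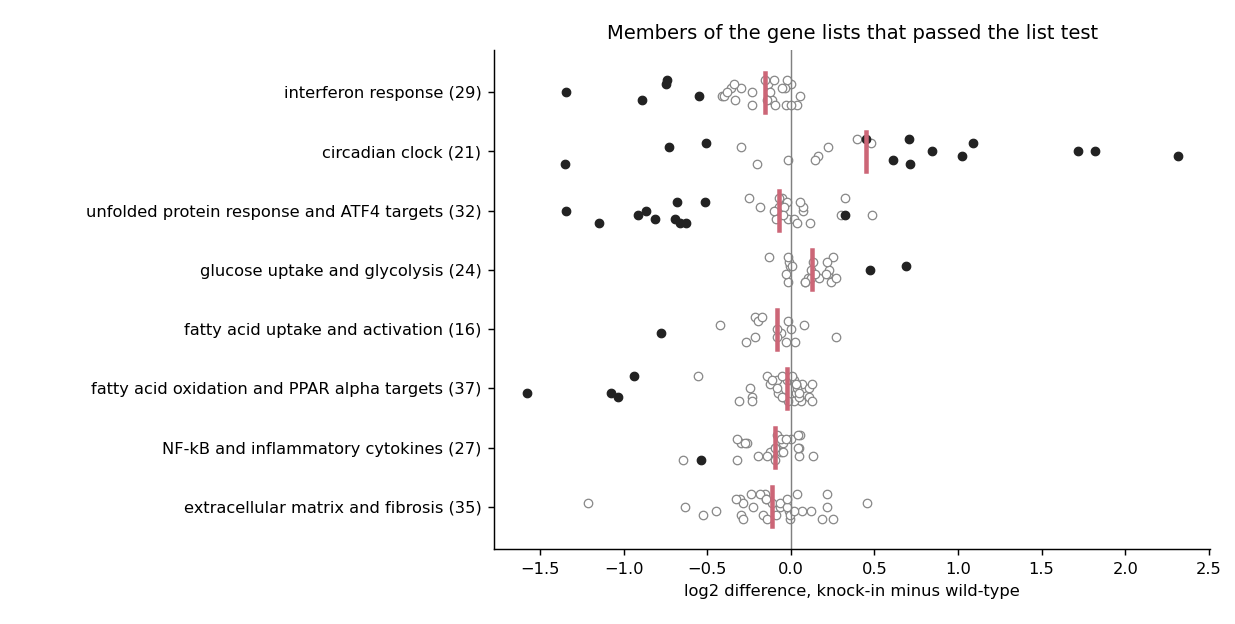
Log2 differences (knock-in minus wild-type) of the measured members of the 8 lists that passed camera at the preset correlation, with the number of members in brackets. Each point is 1 gene, filled where it passed adjusted over the list alone, vertical offsets only separate points, and red bars are list medians, from -0.15 for the interferon list to 0.45 for the clock list.

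In all, 8 of the 39 lists passed camera, 2 higher and 6 lower. Of these 8, 4 passed without wild-type 2 and 6 without knock-in 1. None passed with an estimated correlation, where 0 had an unadjusted p under 0.05, or with fry, which tests whether a list's genes move on balance one way and where 6 had an unadjusted p under 0.05. With 4 arrays these 2 tests can hardly call any list, so the lost calls do not decide whether a list shifted. In fry's test for change in either direction 5 passed, those of fatty acid oxidation, fibroblasts, p53 targets, macrophages and adipocytes. Over all genes, Cdkn1a in the p53 target list was the only member of any list to pass. None of the 12 cell type lists passed, with 1 at an unadjusted p under 0.05, their medians lying between -0.10 (T and B lymphocyte markers) and 0.17 (erythrocyte markers, adjusted p = 0.0718). The largest difference in the erythrocyte list was that of the transferrin receptor Tfrc, 2.62-fold higher. Other probe sets of Tfrc differed by 0.68 and 0.65 on the log2 scale, with SDs of 1.17 and 0.86 in knock-in hearts. The erythrocyte list had an adjusted p of 0.00840 without knock-in 1, 0.0431 after quantile normalization, 0.0322 with averaged probe sets and 0.0314 with the first probe set, but 0.235 without knock-in 2, 0.361, with a median of 0.08, without wild-type 2, and between 0.0622 and 0.0886 in the other fits at the preset correlation. The lymphocyte list was at 0.0339, with a median of -0.16, without wild-type 2, but turned to a median of 0.0200 (adjusted p = 0.972) without wild-type 1 and was at -0.06 (adjusted p = 0.518) without knock-in 2. Of the other lists, immediate early genes passed in opposite directions, higher at 0.0146 (median 0.0116) without knock-in 1 and lower at 0.0243 (median -0.11) without knock-in 2, and cell cycle genes were lower at 0.0236 without knock-in 2 but at 0.290 or above in the other fits. Cardiac contraction genes (median 0.05) and oxidative phosphorylation genes (median 0.02) did not pass, with 0 members past the threshold adjusted over the list alone and 1 and 0 members, respectively, at an unadjusted limma p under 0.05. Median, mean and test differed in sign in 7 lists, none of which passed. One of these, the adipocyte list, had members that passed adjusted over the list alone in both directions, with Car3, Adipoq, Cyp2e1 and Slc36a2 higher and Lipe and Aqp7 lower. Cyp2e1 is also one of the liver genes described next.

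Transcripts characteristic of liver were higher in the knock-in arrays, a set drawn up only after 8 of its genes, Serpina1b and Serpina1c among them, had been seen. Of 52 measured liver genes, 49 were higher in knock-in hearts and 3 lower. Of these, 34 passed adjusted over the list alone and none over all genes. Without the 8 genes seen beforehand, 41 of 44 were higher and 3 lower (median 0.49), and 25 passed adjusted over those 44 alone. Alb, which encodes serum albumin, was at 7.01 and 5.54 in the wild-type arrays and at 8.58 and 9.66 in the knock-in arrays, a difference of 2.84. Only 3 of the 52 had a wild-type mean above the median of all genes, so most were dim in wild-type heart.

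**Figure D3:**
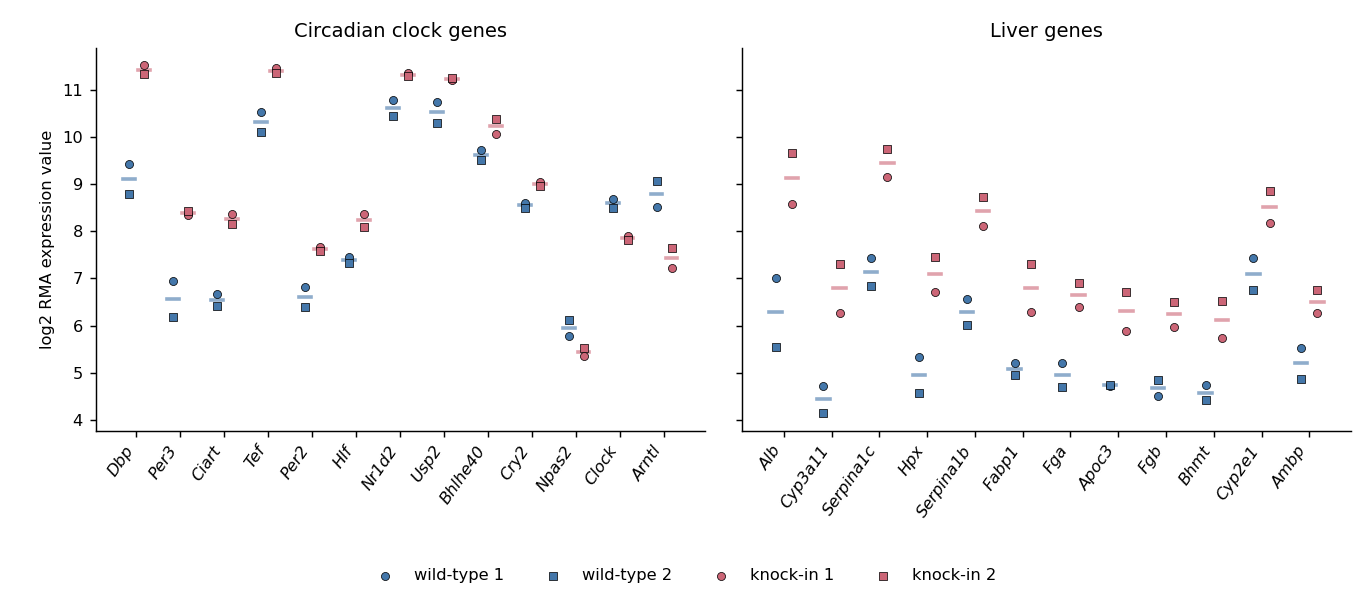
Log2 RMA expression values of the 13 clock genes that passed adjusted over the list alone (left) and of the 12 liver genes with the largest differences (right), where each point is 1 array (circles replicate 1, squares replicate 2) and bars are group means. Alb runs from 5.54 in wild-type 2 to 9.66 in knock-in 2, while Dbp and Arntl lie on opposite sides, at differences of 2.31 and -1.35.

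Genes lying near Gsk3b on the chromosome were over-represented among those of small p. Within 10 Mb of it, 8 of 149 genes (5.37%) had an unadjusted limma p under 0.01, compared with 395 of 17995 genes elsewhere (2.20%), an odds ratio of 2.53 with a 95% confidence interval from 1.06 to 5.17 (p = 0.0183, Fisher's exact test over genes). The 8 were Timmdc1, Tfrc, Phldb2 and Hes1, higher in knock-in hearts by 0.67 to 1.54, and Arhgap31, B4galt4, Plaat1 and Plcxd2, lower with differences from -0.81 to -0.51. Other, dimmer probe sets of Arhgap31 differed by -1.49, -0.29 and 0.02. Another probe set differed by -0.60 for Plaat1 and by -0.30 for Plcxd2. Timmdc1, Arhgap31 and B4galt4 were 7, 10 and 11 measured genes away from Gsk3b on one side, and all 8 are named after their values were seen. The odds ratio was 2.22 (exact p = 0.0832) without wild-type 1, 1.86 (exact p = 0.150) without wild-type 2 and 4.16 (exact p = 0.00888) without knock-in 2. It was 2.07 (exact p = 0.186) with a window of 5 Mb and 2.15 (exact p = 0.0732) among genes above the median. With an intensity trend and robust prior it was 5.78 (exact p = 0.166), where 22 genes passed and 1 of the 149 was counted at the adjusted threshold. A window of 20 Mb gave 2.79 (exact p = 4.57e-04), with 16 of 275 genes counted (5.82%) against 3 of 67 (4.48%) within 5 Mb. The share was thus not highest closest to Gsk3b. Genes counted beyond 10 Mb included Ahsg, Adipoq and Rtp4, members of the liver, adipocyte and interferon lists.

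**Figure D4:**
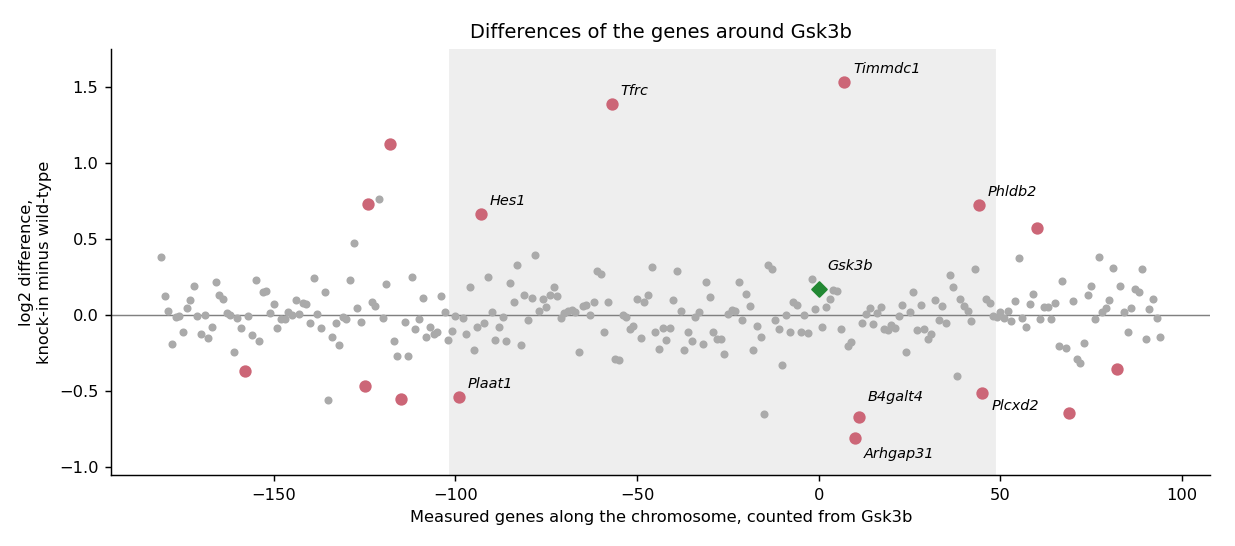
Log2 differences (knock-in minus wild-type) of the measured genes on either side of Gsk3b, by their place along the chromosome counted in measured genes from Gsk3b. Shading marks genes within 10 Mb, large red points have an unadjusted limma p under 0.01, the green diamond is Gsk3b at 0.18, and Timmdc1, at 1.54, has the highest value within the shaded part.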

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

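The 1 gene that passed became 22 with an intensity trend and robust prior, 11 with each array centred, with quantile normalization and with the mean of a gene's probe sets, and 7 among genes above the median. It became 0 with the first probe set listed, with all probe sets, with treat at 1.2-fold and without any 1 array. At an unadjusted limma p under 0.05 there were 1205, 2628 and 260 in the first 3 of these, and between 677 and 1966 without 1 array. The cause was not tested, except that treat asks for a larger difference and 3 arrays are fewer samples. With the replicate number as a block 0 genes passed (1143 unadjusted), and deviations of same-numbered samples correlated at -0.03, so the numbers do not pair the samples. The 8 lists stayed at 8 with the block, became 0 with an estimated correlation and with fry, and the number passing ranged from 5 to 10 without 1 array, with 4 of the 8 kept without wild-type 2 and 6 without knock-in 1. The 49 list members that passed adjusted over the list alone became 79 with trend and robust prior, 48 of them shared. The odds ratio near Gsk3b was 5.78 with trend and robust prior, 6.03 with treat at 1.2-fold and 3.09 with the block. It was 2.15 among genes above the median, 2.07 with 5 Mb and 2.79 with 20 Mb, and ranged from 1.86 to 4.16 without 1 array.

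Of 450 comparisons of the 38 named genes under alternatives, 21 changed sign, 43 newly passed, 7 no longer passed and 379 did neither, where Lpl, at 0.00, was given no direction by a rule set after its values were seen. Cdkn1a is the gene that no longer passed in those 7. With averaged probe sets the differences were -0.19 for Fabp3, -0.17 for Gsk3b, -0.21 for Myh6, -0.12 for Uty and 0.0404 for Xist. With the first probe set they were -0.49 for Myh6, -0.11 for Per3 and 0.0418 for Xist. Quantile normalization gave -0.00288 for Gsk3a and -0.0341 for Myh7. Without 1 array the range was -0.0395 to 0.0710 for Eif2s3y, -0.00135 to 0.0837 for Gsk3a, -0.0851 to 0.113 for Myh7, -0.0590 to 0.529 for Nppb, -0.123 to 0.377 for Ppara, -0.0270 to 0.168 for Sry, -0.00693 to 0.357 for Uty and -0.446 to 0.0570 for Zfy2. RMA values carry no detection calls, so signal over background is unknown for dim genes.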

Other observations

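The tests of the adipocyte list, of the time of day and of other splits of the arrays were chosen only after the result was seen. The lists of liver, clock and fasting genes were drawn up once the leading genes were known, and Timmdc1 and Arhgap31 had been seen among these before the flanking-sequence and probe-binding tests were run. The test of windows around other genes was chosen after the result near Gsk3b was known. Once values had been seen, the flanking-sequence test was made to require a low share of such windows too, the adipocyte test was left undecided where members passed in both directions, and the share of liver genes in 1 array order, first set at 50% of those with an array above the median of all genes (10 of 13), was taken over all of them.

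Genes of glycogen metabolism, a process in which GSK-3 phosphorylates glycogen synthase, were not shifted as a list (22 measured, median 0.11, adjusted p = 0.0964). Adjusted over the list alone, Phka1, a regulatory subunit of the muscle phosphorylase kinase, fell (1.39-fold) and Pygl, the liver isoform of glycogen phosphorylase, rose (1.61-fold), moving with the liver transcripts, of which 49 of 52 were higher in knock-in hearts with a median of 0.57. The branching enzyme Gbe1 differed by 0.59 without passing. The list was at an adjusted p of 0.0127, with a median of 0.19, without knock-in 1 and 0.0396 with an intensity trend and robust prior, but at 0.807, with a median of 0.04, without knock-in 2 and 0.593 with the first probe set, and between 0.0686 and 0.275 in the other fits at the preset correlation. Among the 29 genes of GSK-3 and insulin signalling the smallest p was that of the insulin receptor substrate Irs1, with a difference of -0.59 that did not pass adjusted over the list alone (adjusted p = 0.0582).

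None of the 27 genes of triglyceride synthesis and lipid droplets passed adjusted over the list alone, with 6 higher and 3 lower at an unadjusted limma p under 0.05. The lipid droplet proteins went both ways, with differences of 0.49 for Plin3 and -0.43 for Plin2, and the lipase inhibitor G0s2 differed by 0.45. In the hypertrophy and fetal gene list, where 0 of 26 members passed adjusted over the list alone and 2 were higher and 2 lower at an unadjusted limma p under 0.05, skeletal actin Acta1 was at 12.31 ± 0.14 in wild-type and 13.33 ± 0.57 in knock-in hearts. Of the 16 p53 targets only Cdkn1a passed, while Gadd45a and Fas differed by 0.35 and -0.25. The smallest p in the Wnt target list were those of Birc5 (-0.49) and Jun (0.45), and 0 of its 26 members passed adjusted over the list alone.

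Liver transcripts were higher in the knock-in arrays, with 49 of 52 measured genes higher and a median of 0.57, counting 8 genes seen before the test. Of the other 44, 1 gene, Cyp2e1, was also in the adipocyte list fixed beforehand. If liver RNA had entered the knock-in samples, the 44 liver genes not seen before the test were to have a median above 0.5, and it was 0.49, short of that bound, while 24 of the 44 (54.5%, against 6.12% of all genes) followed the order of arrays seen in the liver genes known before, from wild-type 2 and wild-type 1 to knock-in 1 and knock-in 2. That order needs both knock-in arrays above both wild-type arrays, and 41 of the 44 were higher, against 9139 of all 18193 genes. The share therefore partly restates that these genes were higher, which the 6.12% does not allow for. Values also differed within the groups, with 44 of 52 genes higher in wild-type 1 than in wild-type 2 and 43 of 52 higher in knock-in 2 than in knock-in 1. Without the 8 genes seen before, these counts were 38 and 35 of 44. Over all 18193 genes tested they were 10636 and 9799. For adipose tissue as the source, the adipocyte list had a median of -0.0119, below the bound of 0.2 set against it by more than its spread of 0.0696. Adipose tissue was left open because members passed in both directions. Car3 and Adipoq differed by 2.23 and 1.13, and Lipe and Aqp7 by -0.78 and -0.67. Liver RNA of differing amount may therefore account for the pattern, but with 2 arrays per group it cannot be told apart from an effect of genotype, which was untested, as was the small difference in age.

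The 11 clock genes in phase with Dbp had a median difference of 0.84 and the 5 in phase with Arntl one of -0.50, which places the medians 1.35 apart, although Cry1 of the latter set was higher by 0.48. Hearts collected at different times of day could give this difference, and so could an effect of the genotype on the clock, and no collection times are given, so these cannot be told apart. Different feeding before collection was tested on 29 fasting or glucocorticoid genes, leaving out the 4 that had been seen among the leading genes. The median of the 29 was -0.11, between the bounds of -0.3 and -0.1 set for and against different feeding. At an unadjusted limma p under 0.05, 9 of the 29 were lower and 2 higher in knock-in hearts. Many of them were not unseen, since they were also in lists tested earlier. These included Per1, Angptl4, Acot1, Pnpla2, Plin2, Sesn1, Eif4ebp1, Trim63, Foxo1 and Fbxo32. Feeding stays open, and the 4 members known beforehand (Cdkn1a, Pdk4, Ddit4 and Ucp3) do not bear on it, since they were taken for being lower.

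Differing genes were over-represented within 10 Mb of Gsk3b, with an odds ratio of 2.53. Their share did not peak closest to it, at 4.48% within 5 Mb, 5.37% within 10 Mb and 5.82% within 20 Mb. Against a tendency of differing genes to lie together throughout the genome, windows of 10 Mb around 17562 other genes were taken, which overlap each other. Only 2.96% of them had a share as high as 5.37%. Flanking sequence of another strain kept with the knock-in allele, for which the window had been chosen, is a candidate explanation, but its test rests on this odds ratio and this share of windows and adds nothing beyond them, with an exact p of 0.0832 without wild-type 1 and 0.150 without wild-type 2. Altered probe binding in place of altered transcript level was not decided, since 1 of the 2 other probe sets of these genes with an array above the median of all genes showed at least 50% of the difference. An effect of the kinase on these genes was untested.

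The 3 splits of the 4 arrays into equal groups are too few for a share under 0.05. The real split gave 1344 genes at an unadjusted limma p under 0.05, and the highest of the others gave 708. The other splits put knock-in and wild-type arrays into the same group. Any difference between the real groups then adds to their spread and lowers their counts, so they do not show what chance gives.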
